A study of Homo sapiens with 12 samples.

How the data were processed

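ATAC-seq libraries of U937 cells were analysed: wild type, shKDM6A, shKDM6B and shKDM6A+6B, with 3 replicates each. Each library was deposited as 1 peak list in narrowPeak layout. Per the submitters' processing notes, reads were aligned with BWA to hg38 and peaks were called with MACS2 2.0.10, and per the peak names in the files duplicates were removed before calling. The parameters of the peak caller are not stated, and the control, if any, is unknown. The deposited values per peak are the peak caller's display score, its fold, the ratio of the pileup at the summit over the local background, and -log10 p and -log10 q. The lowest deposited -log10 q of each list was 1.30 to 1.31. These values were used only to rank and filter peaks within a list, because neither read totals nor fragment settings are given and the depth of each library is therefore unknown. No interval on counting error can be given for the same reason.

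Peaks on chromosomes 1 to 22 and X were used, and no list held a peak interval more than once. Peaks of the 12 lists were merged into regions where they overlapped by 1 bp or more. A region was gained in a comparison when it had a peak in 3 of 3 libraries of the first group and 0 of 3 of the second, and lost in the reverse case. No single region can pass a test with 3 against 3 libraries, so regions are given as counts beside those from other splits of the libraries. Numbers of peaks, covered length and widths were compared by exact two-sided permutation tests for 5 pairs of groups (smallest p 0.1) and over the 4 groups (15400 splits, smallest p 6.5e-05). Lists of equal length, the 57223 strongest peaks of each library by -log10 p, served for peak shares, chromosome shares, similarity and genes.

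Gene positions came from RefSeq on GRCh38.p14, which gives the start and end of each gene but neither strand nor exons. A summit was therefore assigned to the protein-coding gene whose body holds it, with the nearest gene end deciding between overlapping genes, or else to the nearest gene within 50 kb. The design had named the nearest transcription start. Where genes overlap, each peak counts for 1 of them: peaks in KDM6B went to an overlapping predicted gene, so KDM6B was not tested and its peaks are given directly. A gene-end peak is one whose summit lies within 1 kb of either end of a gene, in place of a promoter peak, and exons and introns were not separated. With no genome sequence at hand, the planned search for 21 motifs was not run.

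The number of peaks per gene, as log2 with a pseudocount of 0.5, was modelled with limma 3.58.1 (R 4.3.3, with the data.table package at version 1.17.8) with a variance trend, 1 model with group as the only term and 5 contrasts, for the 8571 genes with a mean of 2 or more peaks. Benjamini-Hochberg adjusted p below 0.05 counted as passing. For 23 gene lists fixed before the data were examined (repair pathways, checkpoint, BCL2 family, H3K27 enzymes and partners, HOX, monocyte, granule, stem and progenitor, myeloid transcription factors, AP-1, interferon, inflammatory, MHC class II, drug transport and metabolism, developmental regulators, T and NK cell, B cell, erythroid, epithelial and fibroblast, and ribosomal protein genes), camera with a preset correlation of 0.01 was run, with an estimated correlation and fry as alternatives. An interaction of both knockdowns was added later as a contrast. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

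The rule for named genes was written before the data were examined. It took the 10 largest log2 changes in each direction for each comparison with wild type and the 5 largest for each comparison between knockdowns, among genes that passed and whose change had the same sign in the lists as deposited. It also took list members that passed, or the 2 with the smallest p, and the 3 gained and 3 lost regions with the highest rank in their lists that were gained or lost in lists of equal length too. Of the genes taken from lists in which none passed, only those of shKDM6A against wild type are printed. Near-identical copies are named as uncertain. A fold is not given against a group with 0 peaks in every library.

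Alternatives set before the data were examined were stricter peaks (-log10 q of at least 5), equal-length or deposited lists, scaling by the list total or none, fixed regions of 501 bp, a rule of 2 of 3 libraries, a pseudocount of 1, no filter, assignment within 10 kb, a gene-end window of 2.5 kb, the replicate number as a block, and leaving out each library. Centring on genes of the same 10 Mb, a residual SD bounded from below by its median, and counting merged regions were chosen after seeing the data. The scripts were tested on simulated data. In lists simulated for shKDM6A against wild type, 300 of 300 planted gained and 300 of 300 planted lost regions were recovered, with 64 and 79 others called among 19903. In Poisson numbers simulated for the double knockdown against wild type, with 8446 genes tested, 64% of the genes with a 4-fold gain and 6% with a 2-fold gain were called, as were 22.0% with a fold of 0.25 and 2.08% with a fold of 0.5, and 1 of 8257 unchanged genes.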

Results

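Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in U937 cells, a human monocytic leukaemia line. The 12 libraries fell into 4 groups of 3 replicates: wild type, cells with a hairpin against KDM6A (shKDM6A), cells with a hairpin against KDM6B (shKDM6B) and cells with both (shKDM6A+6B, the double knockdown). KDM6A (UTX) and KDM6B (JMJD3) are H3K27 demethylases, enzymes that remove a methyl mark laid down by the Polycomb complex PRC2. No sample was labelled as carrying a control hairpin, and the labels do not say how the hairpins were introduced. Every difference from wild type may therefore also hold effects of transduction or selection. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries. Each library came as a list of 57223 to 92594 peaks on chromosomes 1 to 22 and X, and its read depth is unknown.

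The target genes were looked at in every library. The KDM6A gene (X:44873188-45112779, hg38) held 6, 4 and 5 peaks in the wild-type libraries, 4, 4 and 5 in shKDM6A, 6, 3 and 4 in shKDM6B, and 5, 7 and 5 in the double knockdown, in lists of equal length. Regions at the lower-coordinate end of KDM6A, X:44872359-44873362 and X:44873713-44874234, had a peak in all 12 libraries. The KDM6B gene (17:7834217-7854796) held 3, 3 and 3 peaks in wild type, 4, 3 and 3 in shKDM6A, 4, 5 and 3 in shKDM6B, and 3, 4 and 3 in the double knockdown. In the lists as deposited, which differ in length, KDM6B held 3, 3 and 3 peaks in wild type and 5, 3 and 3 in shKDM6A. There shKDM6B had 5, 5 and 6 and the double knockdown 6, 8 and 6. KDM6A held 5.33, 6.00, 5.67 and 7.33 peaks on average there, in the order of the groups. A region at the end of KDM6B, 17:7833810-7834285, had a peak in all 12 libraries. KDM6B was left out of the gene test, because peaks inside it were assigned to an overlapping predicted gene. With the peaks nearest to it counted in, KDM6A did not change against wild type in shKDM6A (limma, log2 change -0.13, adjusted p 0.627), shKDM6B (-0.21, adjusted p 0.389) or the double knockdown (0.12, adjusted p 0.635). A hairpin acts on the messenger RNA, so peaks at its gene do not check the knockdown.

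The double knockdown had the most peaks: 91923 ± 1066 per library (SD, n = 3), against 61099 ± 743 in wild type, 65155 ± 3421 in shKDM6A and 69381 ± 16429 in shKDM6B. That was 1.41 times shKDM6A and 1.32 times shKDM6B, and each difference had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. The ratio to wild type was 1.07 in shKDM6A (exact p 0.2) and 1.14 in shKDM6B (exact p 0.7), and over the 4 groups the exact permutation p was 0.0248. In shKDM6B the excess rested on replicate 3, which had 88071 peaks where replicates 1 and 2 had 62849 and 57223. Without shKDM6B replicate 3 the difference from wild type turned to -1063 peaks (exact p 0.8). Peaks covered 14.1 ± 0.423 Mb in wild type, 24.2 ± 0.926 Mb in shKDM6A, 22.7 ± 1.16 Mb in shKDM6B and 38.3 ± 4.57 Mb in the double knockdown (exact permutation p over the 4 groups 0.000195). The narrowest peak measured 114 to 116 bp in the wild-type libraries and 149 to 177 bp in the knockdown libraries except shKDM6B replicate 3, where it was 113 bp.

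**Figure D1:**
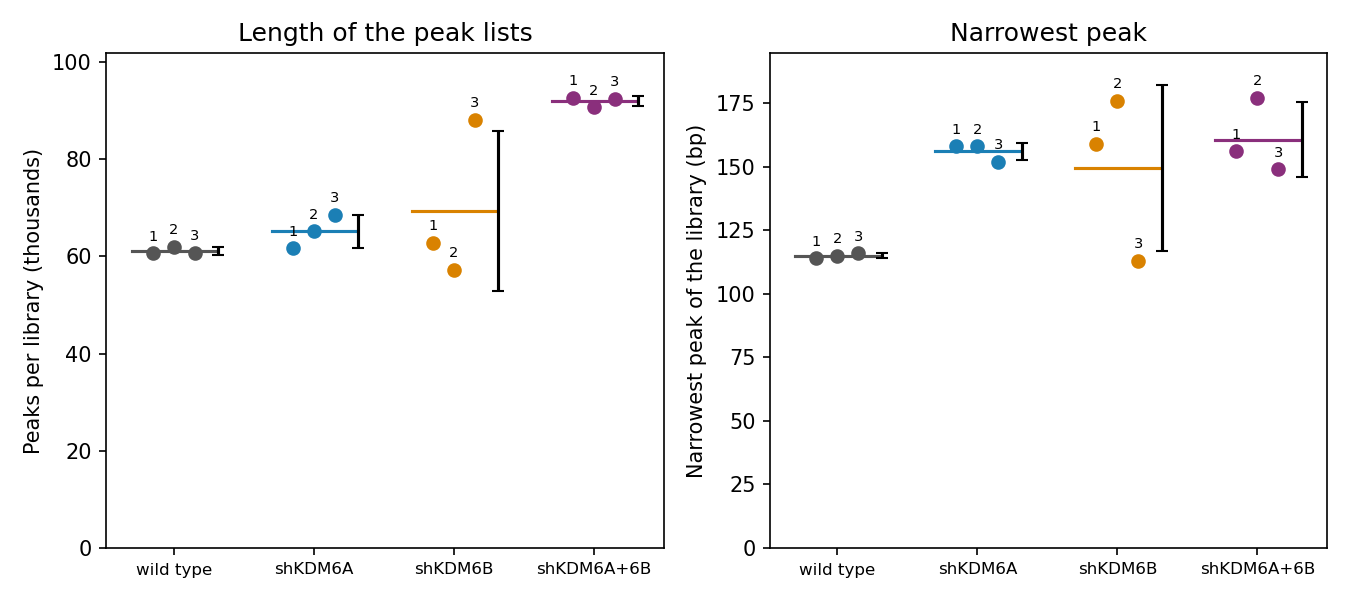
Number of peaks per library, on an axis in units of 1000, (left) and width of the narrowest peak in bp (right) for the 4 groups; points are libraries with their replicate number, lines are group means and bars 1 SD (n = 3). The double-knockdown lists lie between 90694 and 92594 peaks, and shKDM6B replicate 3 stands apart from its group in both plots.

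Averaged over the groups, libraries of 1 group resembled each other more than libraries of different groups. In lists of the 57223 strongest peaks each, the mean Jaccard index of covered bases was 0.136 higher within than between groups (exact permutation p 6.5e-05, the smallest possible). Measured on regions instead of bases, where the difference was 0.0808, the index was 0.707 among wild-type libraries, 0.786 among shKDM6A, 0.702 among shKDM6B and 0.861 among double-knockdown libraries. Between groups it was 0.634 for wild type with shKDM6A, 0.602 with shKDM6B and 0.642 with the double knockdown, and 0.710 for shKDM6A with shKDM6B, 0.786 for shKDM6A with the double knockdown and 0.725 for shKDM6B with it. The shKDM6B libraries were thus less alike than their mean index with either other knockdown, and shKDM6A libraries resembled the double knockdown as much as each other (0.786). The share of peaks within 1 kb of a gene end was 20.7% ± 0.276 in wild type, 19.6% ± 0.262 in shKDM6A, 19.5% ± 0.141 in shKDM6B and 18.7% ± 0.0759 in the double knockdown (SD, n = 3; exact permutation p 0.00052). Gene bodies held 41.9%, 42.1%, 42.5% and 42.3% of the peaks (exact permutation p 0.00091), and the intergenic shares were 37.4%, 38.4%, 38.0% and 39.0% (exact permutation p 6.5e-05).

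Chromosomes were compared because derivatives of a cell line can differ in copy number. The share of peaks differed over the 4 groups for 19 of 23 chromosomes (exact permutation test, Benjamini-Hochberg adjusted). Chromosome 12 held 4.61% ± 0.0292 of the wild-type peaks, 5.11% ± 0.0116 in shKDM6A, 5.17% ± 0.0439 in shKDM6B and 5.22% ± 0.0245 in the double knockdown (SD, n = 3; exact p 0.000714, adjusted 0.00256). Chromosome 5 held 5.02% ± 0.0531, 4.55% ± 0.0434, 4.53% ± 0.0370 and 4.70% ± 0.0371 (exact p 0.000325, adjusted 0.00256). Chromosome 21 held 1.20%, 1.10%, 1.08% and 1.09% (exact p 0.00370, adjusted 0.00709). In each of these 3 chromosomes all 9 knockdown libraries lay on the same side of every wild-type library. The same held for chromosomes 1 and 9 (adjusted p 0.00256 each). The knockdowns did not all move alike on some others: chromosome 8 held 4.57%, 4.63%, 4.23% and 4.39% (exact p 6.5e-05, adjusted 0.00149), chromosome 7 4.94%, 5.14%, 4.96% and 4.61% and chromosome 6 5.96%, 5.52%, 5.91% and 5.46% (exact p 0.000649 and 0.000714, adjusted 0.00256 each). Successive assessed bins of 5 Mb, those with a mean of 20 or more peaks, that shifted the same way in every knockdown group formed 6 segments on chromosomes 5, 8, 12 and 13, sought after the chromosome shares had been seen, and none lies on chromosome 6, 7 or 21. Peaks were more frequent in every knockdown group at 8:1-25000000, 12:65000001-80000000, 12:115000001-130000000 and 13:85000001-100000000, and less frequent at 5:5000001-45000000 and 8:90000001-105000000. The segment at the tip of chromosome 8 had 350 ± 11.5 peaks in wild type and 478 ± 5.13, 445 ± 8.19 and 477 ± 2.65 in shKDM6A, shKDM6B and the double knockdown. That on chromosome 5 had 514 ± 4.51, 375 ± 5.86, 360 ± 3.21 and 388 ± 4.58. It consists of 6 assessed bins, and bins with fewer peaks inside its span were passed over and not assessed.

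**Figure D2:**
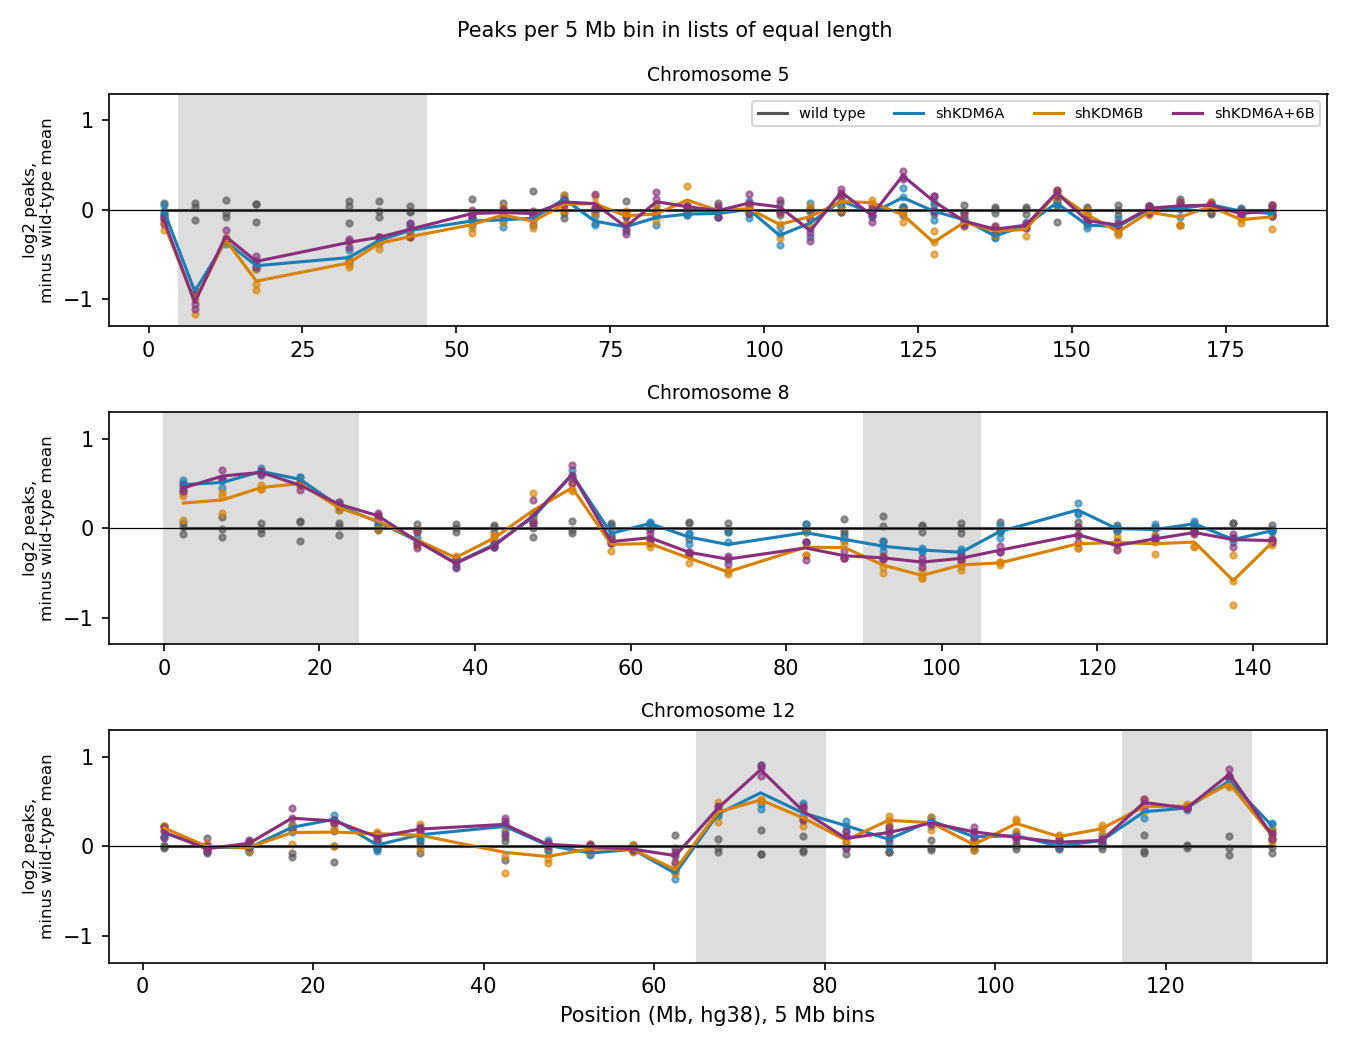
Log2 number of peaks per 5 Mb bin minus the wild-type mean, in lists of equal length, along chromosomes 5, 8 and 12 (position in Mb, hg38); points are libraries, lines group means and grey bands the segments. On chromosome 8 the knockdowns lie above wild type from 0 to 25 Mb and below it from 90 to 105 Mb.

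The comparison of shKDM6A with wild type asks which sites open or close with a hairpin against KDM6A alone. The genes with the largest log2 rise, at a pseudocount of 0.5, were DLC1, a tumour suppressor gene, the tRNA methyltransferase gene TRMT9B and the receptor tyrosine kinase gene FGFR2. DLC1 (8:13083361-13604620) had 6.67 ± 0.577 peaks per library (SD, n = 3), TRMT9B 5 ± 1 and FGFR2 4.67 ± 1.15, where every wild-type library had 0 (limma, adjusted p 1.98e-06, 1.11e-05 and 0.000186). DLC1 and TRMT9B lie in the segment of chromosome 8 with more peaks in every knockdown, and both still passed when each gene was centred on the genes of its 10 Mb. Centring takes out only a shift shared over the 10 Mb, so it cannot decide on a more local difference. The cell adhesion gene NRCAM rose from 0.667 ± 1.15 to 5.67 ± 0.577 peaks (log2 change 2.85, adjusted p 0.0107) and HPGD, whose product breaks down prostaglandins, from 0.333 ± 0.577 to 3.67 ± 0.577 (log2 change 2.52, adjusted p 0.00564). The potassium channel gene KCNK10, the glypican gene GPC3, the phospholipase gene PLCH1, the calcineurin regulator RCAN2 and the kinase gene NUAK1 also rose, by log2 changes of 2.52 to 2.75. Among the genes that lost peaks, LRIG1, a brake on receptor tyrosine kinases, fell from 6.67 ± 2.08 to 1.33 ± 0.577 peaks (log2 change -1.97, adjusted p 0.000950). CRBN, the substrate receptor through which lenalidomide acts, fell from 4.33 ± 0.577 to 1 ± 0 (log2 change -1.68, adjusted p 0.000534). EFEMP1, EMC2, PTGER3, PPA2 and TASP1, the gene of the protease that cleaves KMT2A, fell by log2 changes of -2.40 to -1.56. So did STK3 (-1.62) and C1QTNF3 (-1.53), which lie in segments with fewer peaks, and the hair keratin gene KRT86 (-1.53), whose near-identical neighbours make its assignment uncertain.

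In all, 592 genes rose and 499 fell in shKDM6A among 8571 tested (limma, adjusted p below 0.05). Each of the 20 genes named above lay on the stated side of the wild-type mean in 3 of 3 libraries, which their choice from the same libraries makes likely. Of the 592, 61 lie in the segments with more peaks, and of the 499, 14 lie in those with fewer. These segments hold 197 and 95 of the 8571 tested genes, so such calls were more frequent there than over all tested genes. The segments were chosen by shifts in peak number in these same libraries, so this excess follows from their choice. Without scaling of the deposited lists the split was 505 higher and 145 lower. Without shKDM6A replicate 2 it was 353 and 337, and without shKDM6A replicate 1 it was 373 and 326. PLCH1, PTGER3 and TASP1 did not pass without any of several single libraries, with adjusted p up to 0.126, 0.0877 and 0.0898 (PLCH1 and TASP1 without wild type replicate 1, PTGER3 without shKDM6A replicate 1).

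In several gene groups fixed before the data were examined, members changed in both directions in shKDM6A. JARID2, a partner of the H3K27 methyltransferase complex, fell from 14.7 ± 1.53 to 6.67 ± 0.577 peaks (log2 change -1.08, adjusted p 0.000908), while the methyltransferase gene EZH2 rose (0.80) and WDR5 fell (-0.32) among the 16 tested H3K27 writers, erasers and COMPASS partners. Among 14 stem and progenitor genes TAL1 rose from 0.333 ± 0.577 to 3 ± 0 peaks (log2 change 2.28, adjusted p 0.00663), FLT3 and CD34 rose, and BAALC, in a segment with fewer peaks, fell (-1.04). Of 18 myeloid transcription factors NR4A1 and MAF rose and RUNX1 fell from 27.7 ± 1.53 to 22.3 ± 1.15 peaks (log2 change -0.30, adjusted p 0.0444). Of 20 monocyte and macrophage genes S100A8 and CD4 rose and MARCO fell. In DNA repair FANCC fell among 17 homologous recombination and Fanconi genes, POLM rose and XRCC5 fell among 7 end-joining genes, PARP1 fell among 9 base excision genes and ERCC6 fell among 13 mismatch and nucleotide excision genes. CDKN1A rose among 13 checkpoint genes, and HRK, in a segment with more peaks, rose among 12 BCL2 family genes. Of 7 HOX genes and cofactors HOXA13 rose and HOXA3 fell, and BATF3 fell among 11 AP-1 genes. OASL rose, in a segment with more peaks, and MX2 fell among 8 interferon genes; ABCA3 and SAMHD1 rose and ABCC1 fell among 14 drug transport and metabolism genes. Of 17 developmental regulators PAX2, LHX2 and GATA4 rose and WT1 fell. GATA4 rose from 2.67 ± 0.577 to 6 ± 0 peaks, but it lies in the raised segment of chromosome 8 and had an adjusted p of 0.116 once centred on its neighbours. Of the lineage markers TCF7 and CD5 rose and ZAP70 fell among 8 T and NK cell genes, ANK1 fell among 4 erythroid genes, and EPCAM and CLDN4 rose and ACTA2 fell among 9 epithelial and fibroblast genes.

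No member passed among the 10 granule, 25 inflammatory, 4 MHC class II, 4 B cell and 13 ribosomal protein genes tested. The members with the smallest p, none passing, were CEACAM8, LTF, NFKBIA, IER3, CIITA, HLA-DOA, VPREB1, EBF1, RPS3 and RPL32. Over all 23 lists, 22 of the 273 tested members were higher and 17 lower, and adjusted over the list alone the counts were 26 and 22. Among all 8571 tested genes 592 were higher and 499 lower, so listed genes changed about as often as genes at large. No list passed camera (0 of 23, lowest adjusted p 0.419, 1 list with an unadjusted p below 0.05, and 0 with an estimated correlation). That list was base excision repair, with a median log2 change of -0.32 and an unadjusted p of 0.0182. With limma's fry, 2 lists passed in shKDM6A, base excision repair down (adjusted p 0.0147) and drug transport and metabolism up (adjusted p 0.0200). Median, mean and test differed in sign for the BCL2 family, AP-1 and B cell lists. Of the 39 passing members, 23 also passed in the lists as deposited, and 16 kept their call there, with the spread bounded from below and after centring: FANCC, POLM, ERCC6, JARID2, HOXA3, S100A8, MARCO, CD4, TAL1, BAALC, FLT3, MAF, ABCA3, PAX2, TCF7 and CLDN4.

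At the level of regions, shKDM6A gained 4475 and lost 2378 of 131295 regions, counting those with a peak in 3 of 3 libraries of one group and 0 of 3 of the other. In lists of equal length the counts were 3497 and 2677. The strongest gained regions lay in MAFK (7:1532646-1533420), in CFAP251 (12:121992029-121992533) and at 3:72144790-72145120, where no gene lies within 50 kb. Each had a peak in all 9 knockdown libraries and in 0 of 3 wild-type libraries. The region of CFAP251 lies in a segment with more peaks. Among lost regions, one at the end of KAT6A (8:41929566-41929793), a histone acetyltransferase gene, had a peak in the 3 wild-type libraries, with a fold of 22.2 to 27.6 over background, and in 0 of the 9 others. The others were 5:5770694-5771179, in a segment with fewer peaks, and 14:99055828-99056223, which had a peak in all 3 double-knockdown libraries and in 1 of 3 shKDM6B libraries. Gene ends made up 7.06% of gained and 4.88% of lost regions, against 10.9% of all regions. A gene-end peak was gained at 209 and lost at 95 of 19974 genes, and listed genes that gained one were PARG, TLR2, OASL, TRAF1, CDA, GATA4, GNLY, FCGR3B, TAL1, CCL2 and ITGA2B. PARG and FCGR3B have near-identical copies, so their assignment is uncertain.

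The comparison of shKDM6B with wild type puts the same question to the other demethylase. DLC1 had 4.33 ± 1.53 peaks (SD, n = 3), FGFR2 4 ± 2, the microtubule-binding ligase gene MID2 3 ± 1 and the defensin gene DEFA4 2.33 ± 1.53, where every wild-type library had 0 (limma, adjusted p 6.39e-06, 0.000325, 0.000173 and 0.00372). DLC1 and DEFA4 lie in the segment of chromosome 8 with more peaks, and DEFA4 belongs to a family of near-identical copies, so its assignment is uncertain. NRCAM rose to 5.33 ± 1.15 peaks (log2 change 2.75, adjusted p 0.0124), and KCNK10, HPGD, NUAK1, CST8 and GPC3 rose by log2 changes of 2.24 to 2.37. The developmental coactivator gene EYA1 fell from 5.67 ± 1.15 to 0.667 ± 0.577 peaks (log2 change -2.55, adjusted p 0.0106). HDAC4, a histone deacetylase gene, fell from 5.67 ± 0.577 to 1.33 ± 1.15 (log2 change -2.07, adjusted p 0.0444). HHIP, a hedgehog inhibitor, LRIG1, EMC2, CRBN, KCNJ6, ADAMTS18 and PDIA5 fell by log2 changes of -2.40 to -1.54, and MEGF10 went from 1.33 ± 0.577 peaks to 0 in every shKDM6B library. HHIP, MEGF10 and CRBN did not pass in the lists as deposited (adjusted p 0.0827, 0.145 and 0.0564).

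In all, 565 genes rose and 445 fell in shKDM6B. Each of the 20 genes named lay on the stated side of the wild-type mean in 3 of 3 libraries, again likely from their choice. Without scaling of the deposited lists the split was 594 and 82, with a median shift of 0.12 over all genes. HDAC4 did not pass without any 1 of the wild-type, shKDM6A or double-knockdown libraries (adjusted p up to 0.101, without wild type replicate 3), nor KCNK10 without wild type replicate 1 or 3 or shKDM6B replicate 1 or 2 (up to 0.0726, without shKDM6B replicate 2). Among listed genes, JARID2 fell to 9.33 ± 1.53 peaks (log2 change -0.63, adjusted p 0.0124) and WDR5 fell. TAL1 rose to 2.33 ± 0.577 (log2 change 1.96, adjusted p 0.0130), while the stem and progenitor genes CD38, ERG and BAALC fell. RUNX1 fell to 20 ± 2 peaks (log2 change -0.46, adjusted p 0.00855) and IRF4 fell, while NR4A1 and MAF rose. In the monocyte and macrophage list CX3CR1, CD4 and LILRB4 rose and none fell. EXO1 and POLM rose and PARP1 and ERCC6 fell among the repair genes, and HRK, in a segment with more peaks, rose in the BCL2 family. HOXA3, BATF3 and MX2 fell, IL1A, ABCA3 and CD5 rose, and of the developmental regulators PAX2 and GATA4 rose and PAX5 and WT1 fell, WT1 from 8.33 ± 0.577 to 4.67 ± 0.577 peaks (log2 change -0.78, adjusted p 0.00153). No member passed in the checkpoint, granule, MHC class II, B cell, erythroid, epithelial and ribosomal protein lists. Over the 23 lists 14 of the 273 tested members were higher and 14 lower, and 19 and 17 adjusted over the list alone. With 565 higher and 445 lower among all 8571 tested genes, listed genes did not change more often than genes at large. No list passed camera (0 of 23, lowest adjusted p 0.788, 0 with an unadjusted p below 0.05, and 0 with an estimated correlation), and median, mean and test differed in sign for B cell markers. With limma's fry, the same 2 lists as in shKDM6A passed, base excision repair down (adjusted p 0.0292) and drug transport and metabolism up (adjusted p 0.0164). Of the 28 passing members 19 also passed in the lists as deposited, and POLM, ERCC6, JARID2, HOXA3, LILRB4, TAL1, BAALC, MAF, ABCA3, PAX2 and WT1 kept their call in that setting, with the spread bounded and after centring.

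Regions gained in shKDM6B numbered 4392 and regions lost 1776, and 3108 and 2704 in lists of equal length. Without shKDM6B replicate 2 the gained count was 7801, and without shKDM6B replicate 3 the lost count was 3959. Leaving out a library eases the rule to those that remain, so such counts can only stay or rise. The strongest gained regions lay 30.7 kb from the scavenger receptor gene SCARB1 (12:124745950-124746386), in SIGLEC16 (19:49973987-49974458) and at 13:91144022-91144507, far from any gene, and those on chromosomes 12 and 13 in segments with more peaks. All 3 had a peak in the 9 knockdown libraries and none in wild type. The KAT6A region was lost here too, as was a region in SUMF1 (3:4233466-4233869), which had a peak in 1 of 3 shKDM6A and 3 of 3 double-knockdown libraries. A region 4.39 kb from CEBPE (14:23112782-23113056), a gene of granulocyte differentiation, had a peak in all libraries but those of shKDM6B. Gene ends made up 5.81% of gained and 4.95% of lost regions. PARG, TLR2, OASL, TRAF1, CDA, GATA4 and GNLY gained a gene-end peak and FAP lost one.

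The double knockdown was compared with wild type to ask what hairpins against both demethylases do together. DLC1 reached 8.33 ± 0.577 peaks (SD, n = 3), FGFR2 5.33 ± 0.577, DEFA4 4.67 ± 0.577, TRMT9B 3.67 ± 0.577 and MID2 3.67 ± 0.577, against 0 in every wild-type library (limma, adjusted p 9.64e-07 to 0.000441). DLC1, DEFA4 and TRMT9B lie in the segment of chromosome 8 with more peaks. KCNK10 rose from 0.667 ± 1.15 to 6.33 ± 0.577 (log2 change 3.00, adjusted p 0.00869), HPGD to 5 ± 0 (log2 change 2.93, adjusted p 0.00228) and NUAK1 to 4.67 ± 0.577 (log2 change 2.83, adjusted p 0.00340), and ARHGAP44 and NRCAM rose by 2.71 and 2.69. LRIG1 fell to 1 ± 0 peaks (log2 change -2.22, adjusted p 0.000366) and EYA1 to 1 ± 0 (log2 change -2.02, adjusted p 0.0232). EMC2, ZBTB8OS, PKP1, LANCL2, KRT86, ALMS1 and CUL1, which encodes the scaffold of SCF ubiquitin ligases, fell by log2 changes of -1.87 to -1.46. The neuronal adhesion gene CNTNAP2 went from 5 ± 1.73 to 1 ± 1.73 peaks (log2 change -2.47, adjusted p 0.0459). CNTNAP2, CUL1, LANCL2 and ZBTB8OS did not pass in the lists as deposited (adjusted p 0.347, 0.591, 0.192 and 0.0618), and CNTNAP2, EYA1, LANCL2 and ZBTB8OS did not pass without single libraries, with adjusted p up to 0.147, 0.0680 and 0.0658 without shKDM6A+6B replicates 1, 1 and 2 and 0.0532 without wild type replicate 1.

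In all, 671 genes rose and 618 fell in the double knockdown, 68 of the 671 in segments with more peaks and 20 of the 618 in segments with fewer. Those segments hold 197 and 95 of the 8571 tested genes, so such calls were again more frequent there, which again follows from how the segments were chosen. Without any scaling of the deposited lists 3601 rose and 91 fell, around a median shift of 0.44 over all genes. Without shKDM6A+6B replicates 1, 2 and 3 in turn the totals were 681, 678 and 718 genes. Each of the 20 named genes lay on the stated side of the wild-type mean in 3 of 3 libraries, as their choice makes likely. Among listed genes, JARID2 fell to 6.33 ± 0.577 peaks (log2 change -1.15, adjusted p 0.000496), RUNX1 to 19.7 ± 1.53 (log2 change -0.48, adjusted p 0.00613) and the survival gene BCL2L1 from 10.7 ± 1.15 to 6.33 ± 0.577 (log2 change -0.71, adjusted p 0.0307), while HRK rose in a segment with more peaks. TAL1 rose to 2.67 ± 0.577 (log2 change 2.12, adjusted p 0.00850), with FLT3 and CD34, and MYB and BAALC fell. Among repair genes FANCC, BRIP1, XRCC5, ERCC6 and ERCC1 fell and EXO1 and POLM rose. NR4A1, NFE2 and MAF rose and IRF4 fell among the myeloid factors, S100A8 rose and MARCO fell among monocyte genes, and LTF fell among granule genes. HOXA3, BATF3, MX2, RELB, ABCC1 and SIM1 fell, and OASL, CXCL8, ABCA3, SAMHD1, GATA4, PAX2 and TCF7 rose. The erythroid genes ANK1 and SLC4A1 fell. No member passed in the base excision, checkpoint, MHC class II, B cell, epithelial and ribosomal protein lists. Over the 23 lists 17 of the 273 tested members were higher and 21 lower, and 17 and 24 adjusted over the list alone. With 671 higher and 618 lower among all 8571 tested genes, listed genes changed about as often as genes at large. No list passed camera (0 of 23, lowest adjusted p 0.764, 1 with an unadjusted p below 0.05, and 0 with an estimated correlation), and median, mean and test differed in sign for HOX genes and cofactors. With limma's fry, base excision repair, homologous recombination and Fanconi, and erythroid genes passed, all down (adjusted p 0.0480 each). Of the 38 passing members 15 also passed in the lists as deposited, and ERCC6, BCL2L1, JARID2, HOXA3, TAL1, FLT3, MAF, MX2, ABCA3 and PAX2 kept their call there, with the spread bounded and after centring.

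The double knockdown gained 16841 regions and lost 1230, but 4883 and 2988 in lists of equal length. Of the 16841, 24.9% were also gained in lists of equal length, and of the 1230, 88.9% were also lost there. The strongest gained regions were those at 13:91144022-91144507 and in CFAP251 and one 27.2 kb from the cytokine receptor gene CRLF2 (X:1239658-1240128), with a peak in all 9 knockdown libraries and in 0 of 3 wild-type libraries. The strongest lost regions were the KAT6A region, 5:5770694-5771179 and one 43.1 kb from THBS2 (6:169172563-169172817), which only the 3 wild-type libraries held. Gene ends made up 5.58% of gained and 6.50% of lost regions. A gene-end peak was gained at 513 genes and lost at 79. In the longer lists as deposited, listed genes that gained one in the double knockdown and were not counted in either single knockdown were HRK, S100A8, LILRB4, MMP9, BCL6, IL6, CXCL3, WNT1 and HLA-DRB1, the last uncertain because of near-identical copies. Of these only HRK, MMP9 and WNT1 were also gained against shKDM6B, and none against shKDM6A, so a difference from the single knockdowns is not shown. CHEK1, the checkpoint kinase gene, lost one. Most repair genes had a gene-end peak in all 12 libraries: 28 of 31 homologous recombination and Fanconi genes, 13 of 13 end-joining genes, 20 of 22 base excision genes and 21 of 22 mismatch and nucleotide excision genes. HOX genes and cofactors had one in all libraries at 7 of 25 and in none at 11.

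**Figure D3:**
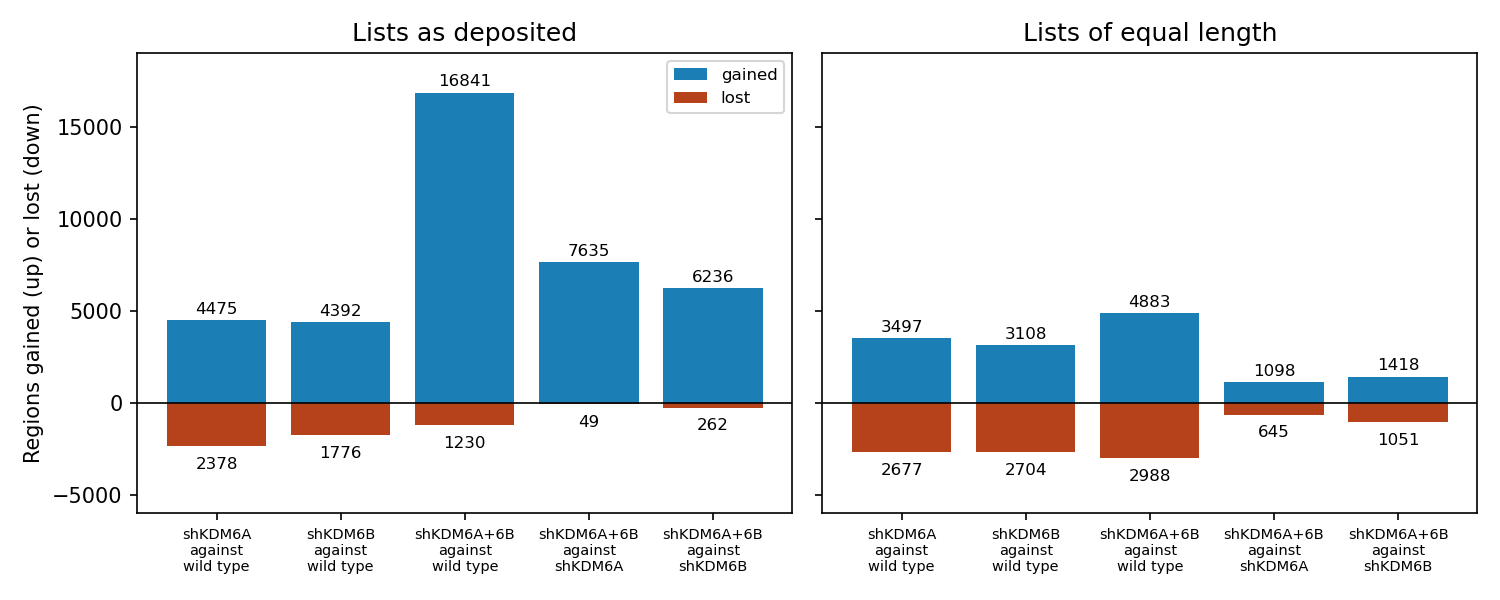
Number of regions gained (up) and lost (down) in the 5 comparisons, with the lists as deposited (left) and with lists of equal length (right). The double knockdown against wild type falls from 16841 to 4883 gained regions once the lists have the same length.

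The double knockdown was compared with each single knockdown to ask what the added hairpin does. Against shKDM6A, MTCL1, a microtubule-binding gene, rose from 1 ± 0 to 4.67 ± 0.577 peaks (SD, n = 3; limma, log2 change 1.78, adjusted p 0.00175), and it was the only one of the 10 named genes that also passed in the lists as deposited (adjusted p 0.0285). ANKS1B rose from 6 ± 1 to 13.3 ± 1.53 (log2 change 1.10, adjusted p 0.0272), and SLCO6A1, ZNF280D and CPD rose by 0.56 to 0.90. CUL1, RPS6KC1, METAP1D, JAZF1 and DAZAP1 fell by log2 changes of -1.34 to -0.49. CPD, DAZAP1, JAZF1, METAP1D, SLCO6A1 and ZNF280D did not pass after centring (limma, adjusted p 0.0759 to 0.145) or with the spread bounded from below (0.0655 to 0.763). In all 10 genes rose and 14 fell. With the deposited lists scaled by their total it was 4 and 1, without scaling 969 and 8 around a median shift of 0.37, and after centring 2 and 3. Without wild type replicate 3 the total was 40 genes and without shKDM6B replicate 3 it was 49. ANKS1B, CPD, METAP1D, RPS6KC1, SLCO6A1 and ZNF280D did not pass without shKDM6A+6B replicate 1 among others (adjusted p up to 0.123, SLCO6A1 without shKDM6A replicate 1). No list member passed, 1 was higher and 4 lower adjusted over the list alone, and no list passed camera (0 of 23, 0 with an unadjusted p below 0.05, lowest adjusted p 0.942, and 0 with an estimated correlation). Median, mean and test differed in sign for the granule, stem, myeloid factor and T and NK cell lists. Regions gained numbered 7635 and lost 49, and 1098 and 645 in lists of equal length. The lost count was 127, 116 and 106 without shKDM6A replicates 1, 2 and 3, and 79 and 82 without shKDM6A+6B replicates 1 and 3. With fewer libraries the rule is easier to meet, so these counts could not fall. MMP8, HLA-DPB1 and NCR1 gained a gene-end peak.

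Against shKDM6B, MEGF10 had 3.67 ± 0.577 peaks where every shKDM6B library had 0 (SD, n = 3; limma, adjusted p 0.000387). HSPA12A rose from 1 ± 0 to 3.33 ± 0.577 (log2 change 1.34, adjusted p 0.0400), and ARMH4, ADAMTS18 and EEF1AKMT4-ECE2, a read-through of overlapping genes whose assignment is uncertain, rose by 1.22 to 1.34. DISP1, PKP1, SLC4A1, KIF25 and GMDS fell by log2 changes of -1.34 to -0.89. ARMH4, GMDS and HSPA12A did not pass after centring (limma, adjusted p 0.0548 each). PAX5 rose from 8 ± 0 to 13 ± 0 peaks (log2 change 0.67, adjusted p 0.0240) and WT1 from 4.67 ± 0.577 to 7.33 ± 0.577 (log2 change 0.60, adjusted p 0.0303), while XRCC5, RELB, CD5 and SLC4A1 fell by -1.18 to -0.46. None of these 6 list members passed in the lists as deposited. In all 26 genes rose and 46 fell. With the deposited lists scaled by their total it was 27 and 5, without scaling 344 and 3 around a median shift of 0.32, and after centring 12 and 10. With only peaks of -log10 q of at least 5 it was 136 and 88, and with the spread bounded from below 88 and 62. In these settings more genes rose than fell, the reverse of the main result. The total was 120 without shKDM6B replicate 3 and 25, 34 and 32 without shKDM6A+6B replicates 1, 2 and 3. ARMH4, DISP1, GMDS, HSPA12A, PKP1 and SLC4A1 did not pass without shKDM6A+6B replicate 1 among others (adjusted p up to 0.153, HSPA12A without shKDM6A+6B replicate 2), and of the 10 named genes only ADAMTS18 and KIF25 passed in the lists as deposited. Over the 23 lists 2 members were higher and 4 lower, and 4 and 9 adjusted over the list alone. No list passed camera (0 of 23, lowest adjusted p 0.512, 2 with an unadjusted p below 0.05, AP-1 and stem and progenitor, and 0 with an estimated correlation). With limma's fry, drug transport and metabolism passed, down (adjusted p 0.0284). Median, mean and test differed in sign for the end-joining, mismatch and nucleotide excision, BCL2, HOX, monocyte, granule and MHC class II lists. Regions gained numbered 6236 and lost 262, and 1418 and 1051 in lists of equal length. Without shKDM6B replicate 3 the gained count was 14238, and without replicates 1 and 2 of shKDM6B the lost counts were 560 and 850. Here too the rule is easier to meet with fewer libraries, so the counts could not fall. HRK, ELANE, MMP9, CCL2, HLA-DPB1, WNT1 and FAP gained a gene-end peak.

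The single knockdowns overlapped. Of the 4475 regions gained in shKDM6A, 2287 were also gained in shKDM6B (51.1%), among them those at MAFK, CFAP251, SIGLEC16 and SCARB1, and of the 2378 lost 1273 were shared (53.5%), the KAT6A region among them. Independent lists of these lengths would share 150 gained and 32.2 lost regions. These values treat every region as able to change. A region with a peak in all 12 libraries can be neither gained nor lost, so they are too low. Unchanged groups simulated against the same wild-type libraries shared 68.4 and 74.1 on average over 50 simulations. Those groups gained only 399.5 and lost only 409 regions on average, so their overlaps are not matched in size. At the gene level 363 genes rose in both, DLC1, FGFR2, NRCAM, KCNK10 and TAL1 among them, and 248 fell in both, LRIG1, CRBN, EMC2, JARID2 and RUNX1 among them, where independent lists would share 39.0 and 25.9. Simulated unchanged groups shared 0 in 20 simulations, but almost no gene passes in such groups. That 0 was therefore fixed in advance and gives no value to compare with. In the double knockdown 95.2% of the regions gained in shKDM6A and 86.8% of those gained in shKDM6B were gained as well, with far longer lists, but 73.5% and 65.1% in lists of equal length. Of the regions lost in the single knockdowns 47.2% and 51.4% were lost in the double knockdown too, and 79.2% and 73.7% in lists of equal length. Part of these overlaps can come from the shared wild-type libraries, which are too few to be split.

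Regions were also counted that set 1 group apart from the 9 libraries of the other groups. Wild type held 866 regions found in no knockdown library, the KAT6A and THBS2 regions among them, and lacked 2258 found in all 9, the MAFK, SIGLEC16 and CRLF2 regions among them. The double knockdown held 2178 alone and lacked 2. For shKDM6A the counts were 14 and 81, and for shKDM6B 149 and 97, with the CEBPE region among the 97. In lists of equal length they were 1628 and 1474 for wild type, 164 and 42 for the double knockdown, 99 and 39 for shKDM6A and 318 and 134 for shKDM6B. Leaving out a library eases the rule to those that remain, so these counts can then only stay or rise. The rises alone therefore do not show that a count rests on 1 library. Regions held by the double knockdown alone numbered 3388, 3418 and 3870 without its replicates 1, 2 and 3 and 3486 without shKDM6B replicate 3. Regions held by shKDM6A alone numbered 43, 41 and 35 without its replicates 1, 2 and 3, and regions lacking in shKDM6A alone 152 and 186 without its replicates 2 and 3 and 131 and 177 without shKDM6B replicates 1 and 2. Regions held by shKDM6B alone numbered 353 and 536 without its replicates 1 and 2, and regions lacking in it 146 and 648 without its replicates 1 and 3 and 147 without shKDM6A replicate 1.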

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

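The tests of list length, of wild-type cells, of a regional change, of the fragment model within segments and of more open sites, and the counts of other splits except the one for the interaction, were chosen only after the results had been seen.

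A difference between groups drew attention to 422 genes in which the change from shKDM6A to the double knockdown differed from the change from wild type to shKDM6B (limma, adjusted p below 0.05, 196 higher and 226 lower, 1638 at an unadjusted p below 0.05). Of 611 genes that changed alike in both single knockdowns, JARID2, TAL1 and LRIG1 among them, 529 changed the same way in the double knockdown. Of the 611, 320 had an interaction past the threshold. How these genes depart from the sum of the single changes was not tested, since they were chosen by changes that enter the interaction themselves. A difference from wild type that all knockdown groups share gives such an interaction by itself. The 422 genes therefore do not show that the knockdowns act on each other. Of 100 splits of the 12 libraries 1, the real one, gave as many genes, and the highest other gave 187. Those splits mix wild-type with knockdown libraries, so they do not set an interaction apart from such a shared difference. The count was 259 without shKDM6A replicate 2 and 189, 225 and 203 without shKDM6A+6B replicates 1, 2 and 3. Without scaling of the deposited lists 82 genes were higher and 25 lower, so the majority turned. After centring it was 130 and 142, and with no filter 358 and 374.

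Signal outside the sequences compared drew attention to the double knockdown, which had 75.0 ± 1.73 peaks per library outside chromosomes 1 to 22 and X (SD, n = 3), against 40.7 ± 3.06 in wild type, 34.0 ± 2.65 in shKDM6A and 42.3 ± 12.7 in shKDM6B. As a share of all peaks this was 0.0815% ± 0.00167, against 0.0665% ± 0.00515 in wild type. The difference was not tested, and the deposited lists were longer in the double knockdown.

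Regions gained or lost alike in all 3 knockdowns, such as those at MAFK, SIGLEC16 and CRLF2 and the lost region of KAT6A, numbered 2258 and 866 in the lists as deposited. Longer lists in the knockdowns are argued against as the whole cause, since lists of equal length still gave 1474 gained regions, a count of 65.3% of the 2258, and 1166 of the 2258 themselves (51.6%) were gained there too. A narrower fragment setting of the wild-type lists stays open: shKDM6B replicate 3, the only knockdown library with peaks as narrow, held 1.28 times the share of the lower of its sister libraries of the 4259 regions gained in shKDM6A and the double knockdown. That value, and the ratio of 0.951 in lists of equal length, met the bound set against this explanation, but both rest on a single library, so they do not decide. Wild-type cells that differ from the cells with hairpins for reasons other than the knockdowns cannot be told apart from an effect of either demethylase for the 2258 regions, since no control hairpin is among the samples.

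Neighbouring 5 Mb bins were shifted together in all 3 knockdowns in 6 segments, with DLC1, TRMT9B, DEFA4 and GATA4 in the raised segment of chromosome 8 and STK3 and BAALC in the lowered one. A candidate explanation is a copy number difference between the wild-type cells and the derivatives. It predicts that sites open in all 12 libraries rank higher in raised than in lowered segments in the knockdowns, and the shift was 17.0 to 19.2 percentile points in the 9 knockdown libraries, -0.348 to 0.313 in wild type, with a largest SD of 0.631 in a group (672 and 372 regions). The segments were chosen from lists cut by the same ranking in the same libraries, so that choice favours this direction. A regional change of accessibility would give the same values, and all 9 knockdown libraries lay beyond every wild-type library in each segment, partly because the segments were chosen for it, so the explanations cannot be told apart. Fragment width was set against the shift in shKDM6B replicate 3, which was 0.949 of that of its sister libraries, but 1 library does not decide.

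More peaks in the double knockdown may reflect deeper libraries. Among peaks with a fold near 10 the median -log10 p was 23.4 ± 3.71 in the double knockdown, 18.3 ± 0.198 in shKDM6A, 18.8 ± 1.44 in shKDM6B and 17.3 ± 0.0391 in wild type (SD, n = 3), and the lowest double-knockdown library exceeded the highest shKDM6A library by 1.93, although this value also moves with the fragment setting. More open sites cannot be told apart from depth: with lists of equal length 1743 regions differed between the double knockdown and shKDM6A, and 1815 between the single knockdowns. A biological effect of losing both demethylases stays open.

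Other splits of the libraries were counted. With 6 libraries only 10 splits exist, too few for a share below 0.05. The real split gave the highest count, 1 of 10, for regions gained or lost in every comparison: 6853 in shKDM6A against wild type (highest other 563), 6168 in shKDM6B (993), 18071 in the double knockdown (405), 7684 between the double knockdown and shKDM6A (626) and 6498 between it and shKDM6B (1600). For genes the counts were 1091 (highest other 7), 1010 (22), 1289 (4), 24 (6) and 72 (10) in the same order. For gene lists the real count was 0 each time, so all 10 of 10 splits gave as many, and the highest other was 1 in the double knockdown against wild type and 0 elsewhere. Splits of 3 against 9 libraries allow a share below 0.05. For wild type 2 of 100 splits held as many regions alone as the real 866 (highest other 2178, the split of the double knockdown) and 1 lacked as many as 2258 (highest other 219), both shares below 0.05. The share was also below 0.05 for the 2178 regions of the double knockdown (1 of 100, highest other 866) and the 149 of shKDM6B (3 of 100 drawn, highest other 339). The draw for shKDM6B missed larger splits: of all 220, 8 (3.64%) held as many as the 149, with 2178 in the split of the double knockdown the highest. These shares were not adjusted for the number of counts tried, and the splits do not test list length. The share was 0.05 or more for the 14 held (40 of 100, highest other 2178) and 81 lacking in shKDM6A (6 of 100, highest other 219), the 97 lacking in shKDM6B (5 of 100, highest other 185) and the 2 lacking in the double knockdown (52 of 100, highest other 2258), so chance stays open for these. Over all 220 splits the 81 were reached in 15 and the 97 in 11, the real one included, with 2258 in the split of wild type the highest. Counts several times the real one, 2178 and 2258, point to a structure of the samples. In lists of equal length wild type still held 1628 and lacked 1474 regions alone, while the double knockdown held 164 and lacked 42, fewer than shKDM6B (318 and 134).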

How the results depend on the processing

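Centring on genes of the same 10 Mb, the bounded SD, merged regions and the interaction contrast with its alternatives were chosen only after the results had been seen. Of 719 values tried for the main results 623 kept their direction and their side of the threshold or stayed within 1.5 times. The other 96 follow, and the cause of a change was not tested unless a cause is given. The planned motif shares, with their windows and list lengths, were not run, since no genome sequence was at hand.

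With lists of equal length, which takes out list length, lost regions in shKDM6B numbered 2704, gained and lost regions 4883 and 2988 in the double knockdown against wild type, 1098 and 645 against shKDM6A and 1418 and 1051 against shKDM6B. Regions held and lacking were 1628 and 1474 for wild type, 99 and 39 for shKDM6A and 164 and 42 for the double knockdown, and 318 were held by shKDM6B. With a rule of 2 of 3 libraries, which admits more regions by construction, gained and lost counts were 8855 and 5406 in shKDM6A, 10472 and 4056 in shKDM6B and 26225 and 2750 in the double knockdown against wild type, 16090 and 251 between it and shKDM6A, and 13077 and 1205 between it and shKDM6B. With regions of fixed width 1998 were lost in the double knockdown against wild type, 219 against shKDM6A and 429 against shKDM6B, 22 were held by shKDM6A alone and 28 lacking in the double knockdown alone. With only peaks of -log10 q of at least 5, 166 regions were lost between the double knockdown and shKDM6B, 0 were lacking in the double knockdown alone, and 2666 genes changed in it against wild type and 224 against shKDM6B.

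With the deposited lists scaled by their total 2083 genes changed in the double knockdown against wild type, 5 against shKDM6A and 32 against shKDM6B, where 1 gene list passed. Of the genes called in the main results, 659 of 1091, 565 of 1010, 696 of 1289, 1 of 24 and 2 of 72 were called again, in the order of the report, and 3, 4, 86, 3 and 6 had the opposite sign. Without scaling, 650 genes changed in shKDM6A, 3692 in the double knockdown against wild type, 977 against shKDM6A and 347 against shKDM6B, 1 gene list passed against shKDM6B, and 107 genes had an interaction. There, the median gene was raised with the longer lists (0.44 in the double knockdown against wild type), although 91 genes still fell in that comparison. CNTNAP2 (log2 change 0.24) and CUL1 (0.22) in the double knockdown against wild type, CUL1 (0.29), DAZAP1 (0.34), JAZF1 (0.11) and RPS6KC1 (0.24) against shKDM6A, and GMDS (0.047) and SLC4A1 (0.10) against shKDM6B reversed. With only peaks of -log10 q of at least 5, SLC4A1 reversed too (0.034 against shKDM6B). After centring 5 genes changed against shKDM6A, 22 against shKDM6B, and 272 had an interaction. With no filter, which tests more genes, 67 and 145 changed against shKDM6A and shKDM6B and 732 had an interaction. With the bounded SD 150 genes changed against shKDM6B, and 659, 593, 780, 4 and 28 of the genes called in the main results were called again. That setting gave an adjusted p of 1.49e-32 for TRMT9B in shKDM6A, too small to be believed with 3 libraries per group, so it is only a rough check. The main model also gave very small values. With each library left out in turn, EMC2 in shKDM6A had a limma adjusted p of at most 4.13e-12, not to be taken literally either. With fry 2 gene lists passed in shKDM6A and 2 in shKDM6B, 3 in the double knockdown against wild type and 1 against shKDM6B: the base excision repair list was called down in all comparisons with wild type, drug transport up in both single knockdowns and down in the double knockdown against shKDM6B, and homologous recombination and Fanconi and erythroid lists down in the double knockdown against wild type. With camera at an estimated correlation 0 lists passed in every comparison (base excision repair adjusted p 0.872, 0.839 and 0.879 by limma against wild type), and of its 9 genes 1, 1 and 0 passed. Fry tests whether a list's genes move 1 way on balance and compares them with no other genes.

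Leaving out each library in turn leaves fewer samples. Genes changed numbered 690 (without shKDM6A replicate 2) to 1181 (without shKDM6B replicate 3) in shKDM6A, 678 (without shKDM6A+6B replicate 2) to 1377 in the double knockdown against wild type, 19 to 49 against shKDM6A, 25 to 120 against shKDM6B, and 189 to 542 for the interaction. The difference in peaks between shKDM6B and wild type ranged from -1063, without shKDM6B replicate 3, to 14361, without shKDM6B replicate 2. Counts of regions could only stay or rise by construction, because the rule then asks only for the libraries that remain. Gained regions ranged from 4392 to 7801 in shKDM6B and from 6236 to 14238 between the double knockdown and shKDM6B. Lost regions ranged from 1776 to 3959 in shKDM6B, from 49 to 127 between the double knockdown and shKDM6A and from 262 to 850 between it and shKDM6B. Regions held alone ranged from 14 to 43 for shKDM6A, 150 to 536 for shKDM6B and 2282 to 3870 for the double knockdown, and regions lacking alone from 84 to 186 for shKDM6A and 99 to 648 for shKDM6B.

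The replicate numbers did not clearly pair the samples. Of 18 pairs with the same number 1 deviated together with a correlation above 0.1, the mean was 0.0249 and the highest 0.111. Of 36 pairs with different numbers 0 exceeded 0.1, the mean was -0.0125 and the highest 0.0536. Pairs with the same number were thus slightly more alike on average, and a weak pairing stays open. With the number as a block 1015, 950, 1211, 18 and 50 genes changed in the 5 comparisons, 906, 848, 1090, 14 and 44 of them called in the main results, 314 had an interaction, and the exact permutation p for peaks over the 4 groups was 0.0434. No count of genes moved by more than 1.5 times with the block, but 13 of the 80 results of named genes no longer passed: PTGER3 and TASP1 in shKDM6A, HDAC4 in shKDM6B, CNTNAP2 and ZBTB8OS in the double knockdown against wild type, ANKS1B, CPD, METAP1D, RPS6KC1, SLCO6A1 and ZNF280D against shKDM6A, and ARMH4 and DISP1 against shKDM6B.

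For the 80 results of the named genes in the comparisons 1428 of 1659 values kept direction and side of the threshold and 9 reversed. DLC1, FGFR2 and LRIG1 against wild type were not among those that reversed. Read depth is unknown, so neither the number of peaks nor their p can be set against it, and a peak missing from a list does not show that a site was closed.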

Other observations

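Values that belong to no comparison of the report are given here, and the correlations of neighbouring bins were chosen after the results had been seen. Of 131295 regions 32892 (25.1%) had a peak in all 12 libraries, and 30352 in 1. Gene-end peaks were found in all 12 libraries at 9898 of 19974 protein-coding genes and in none at 7088. Among the listed genes, 38 of 40 ribosomal protein genes and 17 of 30 monocyte genes had one in all 12, while 40 of 50 developmental regulators had none. Neighbouring 5 Mb bins were correlated in their change against wild type (r 0.411 in shKDM6A, 0.396 in shKDM6B and 0.429 in the double knockdown, across 530 bins, which are not independent replicates), and also between the double knockdown and shKDM6A (0.380) and shKDM6B (0.389), where 0 genes called lay in the segments. Regions gained in all 3 knockdowns numbered 2258 with the lists as deposited and 1474 in lists of equal length, and regions lost in all 3 numbered 866 and 1628.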
